A study of Mus musculus with 4 samples.

How the data were processed

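Single-cell 3' RNA counts were analysed from 4 libraries of mouse B16-F10 tumours: transferred Pmel-1 cells and endogenous CD45+ cells, each from an arm given IRF4-transduced and an arm given GFP-transduced Pmel-1 cells. Groups were taken from the labels, with 1 library in each. Per the labels' protocols the libraries were made with a 10x Genomics 3' kit of version 3. The same protocol text also speaks of a single-nucleus suspension, although the material was sorted as cells. Barcodes were treated as cells here, with median mitochondrial shares of 3.72%, 4.02%, 3.86% and 3.702% in the transferred IRF4 and control and the endogenous IRF4 and control libraries, and this was not settled. The counts deposited by the authors are whole UMI counts per gene and barcode, not normalised. Per the submitters' processing notes they were made with Cell Ranger 3.0.2 and STAR 2.6 against mm10. The annotation behind the counts is not given in the sources used here. The files name 28692 genes by Ensembl identifier and symbol, and 58 symbols belong to more than 1 identifier. Coordinates come from the GENCODE vM21 annotation of the same assembly.

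A barcode was kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs, which left 15126 of 17711 barcodes. Doublets were called per library with Scrublet at an expected rate of 0.06, and the call did not work: it marked 6 of 15688 barcodes (0.0382%). An added alternative therefore left out the 6% of cells with the highest doublet scores in each library. Cluster 5, with T cell and myeloid transcripts together and a median of 76407 UMIs, stayed unnamed. Cells of all libraries were clustered together on log counts per 10000, with 2000 variable genes (Irf4, ribosomal, mitochondrial and antigen receptor variable genes left out), 30 components, 15 neighbours and Leiden resolution 1, which gave 26 clusters. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.

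Clusters were named from 20 marker lists fixed before the data were examined, by a rule that was not. In all, 3 rules were tried, each after the markers and the cells per library of the clusters had been seen, and the third was used. The first asked for markers at a log2 fold of at least 1 against the other clusters. The second counted a marker where it reached at least 25% of its highest cluster level in at least 10% of cells, and asked for at least 50% of the markers and at least 3. It left T and NK clusters unnamed above 1000 CPM of Lyz2 and CD8 clusters above 50 CPM of Cd4, and did not count Ly6c2, a member of a T cell list, as a monocyte marker in T cell clusters. The third also left a CD4 T cluster unnamed above 150 CPM of Cd8a, a limit set after cluster 13 was seen, which held 63 endogenous cells in the IRF4 arm, 270 in the control arm, and 1 and 25 transferred cells. Monocyte and macrophage markers were joined into 1 class. No CD8 cluster has a CD8 marker among its 10 leading genes by fold. Unnamed clusters held 9.52% and 14.9% of kept transferred cells and 14.7% and 19.4% of kept endogenous cells in the IRF4 and control arms. CD8 T-like cells numbered 469 and 1954 among transferred and 1888 and 544 among endogenous cells, with 12102347, 52311265, 33190100 and 8105430 UMIs.

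UMIs were summed over the cells of a class per library and scaled to CPM. Log2 ratios used a pseudocount of 1 CPM, and printed ratios are plain ratios of CPM. Levels have exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, at 95%, all for counting error only. Where no cell of a class had a UMI, the limit given is 3 counts of the total instead of such an interval, and it limits cells with a UMI, not cells expressing the gene. With 1 library per group, cells were not used as replicates, and no test, p-value or count of changed genes was made. A gene with 0 UMIs in 1 library is given a bound against a floor of 3 counts. A list member was measured at 10 CPM or more in either library and called higher or lower at a ratio of 1.5 on the log2 scale with the pseudocount. The median of a list is set among 10000 random lists of the same size matched on mean CPM in 20 bins, as a description of these libraries. A class was compared with at least 100 cells in each library. To compare shares of cells with a UMI, each cell was thinned to 2000 UMIs. B-like and monocyte or macrophage-like cells served as the background, and free RNA of the transferred libraries themselves was not measured.

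Genes named in the text follow a rule fixed before the data were examined. The primary genes were Irf4, Pdcd1, Havcr2, Lag3, Tox, Tcf7, Il7r, Gzmb, Ifng and Mki67. The 10 highest and 10 lowest ratios were named for transferred cells between arms and 5 of each elsewhere, among genes with at least 50 CPM and 20 UMIs in the higher library. Ribosomal, mitochondrial, predicted and antigen receptor genes, X-inactivation and Y genes, markers of other cell types and genes over 5 times higher outside the class were left out of the ranking. Of each list, the 4 members with the largest ratios could be named. Hbb-bs, Lyz2, Cd74, Xist, Ddx3y and Trbv14 were named outside this rule, as were the leading genes of clusters. Genes with near-identical copies, such as the histone genes, Hspa1a and Hspa1b, Ifit3 and Ifit3b, and Bcl2a1b and Bcl2a1d, are uncertain where reads could be split between copies.

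The lists fixed beforehand were those of cytotoxic, inhibitory receptor and exhaustion, stem and memory, proliferation, cytokine and chemokine, terminal effector, tissue residency, TCR early activation, IRF4 partners and targets, costimulation and cytokine receptors, chemokine receptors and adhesion, glycolysis, respiratory chain, biosynthesis and Myc, type I interferon, interferon-gamma, unfolded protein, apoptosis and heat shock genes for CD8 T-like cells. MHC class II, suppressive or repair, and inflammatory lists were for myeloid cells and a maturation list for NK-like cells. A list of Treg effector genes was not run, since Treg-like cells numbered 83 in the control arm. Some genes stand in more than 1 list, such as Prdm1 and Zeb2.

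The steps were tested on simulated counts drawn from the transferred and the endogenous CD8 comparisons, over 2835 and 3017 genes with 200 changed. Genes changed 2-fold or 0.5-fold passed a ratio of 1.5 in 100% of cases in both, and genes changed 1.2-fold or unchanged in 0%. Intervals covered the true ratio for 95.1% and 95.5% of genes, for counting error only. Spread between cells or libraries was not tested. Of 40 unchanged lists, 0% and 2.5% lay outside the middle 95% of random lists, and a list changed 2-fold lay at percentile 100 in both. Alternatives fixed beforehand covered scaling, pseudocount, filters on genes and cells, doublets, equal cell weights, thinning, clustering resolution and the choice of CD8 cells. Others, added after the data were seen, covered the naming rules, single clusters, doublet scores, Trbv14 (the beta chain segment of the Pmel-1 receptor), Xist, cycling cells and single cells rich in granzymes. The choice of results to stand for a comparison first favoured those that did not move, and was corrected before values were read.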

Results

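Mouse B16-F10 melanoma, a transplantable tumour line of C57BL/6 mice, was treated on day 3 with Pmel-1 CD8 T cells. These T cells carry a transgenic receptor for the melanoma antigen gp100 and were transduced with IRF4 and GFP or with GFP alone. IRF4 is a transcription factor induced by T cell receptor signalling that partners BATF in effector CD8 T cells. On day 14 the transferred cells and the endogenous CD45+ cells of both arms were sorted from the tumours and profiled by droplet 3' RNA sequencing, with 1 library per group and 4 libraries in all. The title of the series names the question as how IRF4 bears on the anti-tumour immunity of CD8 T cells. The transferred libraries held 715 barcodes in the IRF4 arm and 3640 in the control arm, with 16664323 and 94686409 unique molecular identifiers (UMIs). The endogenous libraries held 6981 and 6375 barcodes, with 81843816 and 84211837 UMIs. After filtering, 567, 2513, 6370 and 5676 cells remained, in that order, at median depths of 16322, 19963, 8434.5 and 10521 UMIs. No group had a replicate library, so no difference between groups was tested. Levels are given as CPM, the UMIs of a gene summed over the cells of a class and scaled to the total of the class, and every interval is a 95% interval for counting error only. Measured members of a gene list are counted as higher or lower at a ratio of at least 1.5, and list medians are log2 ratios of the IRF4 arm over the control arm unless stated otherwise. The percentile of a list sets its median among 10000 random lists of the same size matched on expression. A range gives the lowest and highest value over the alternative settings, for every median and for counts that reached at least 3 members and moved by over 1.5 times. Some settings measured more members.

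Irf4 (ENSMUSG00000021356, chromosome 13, 30749226 to 30766976, plus strand, mm10) itself was measured at nearly the same level in CD8 T-like cells of both transferred libraries, at 28.01 against 24.9 CPM in the IRF4 and control arms, a ratio of 1.12 (0.994 to 1.27). After each cell was thinned to 2000 UMIs, 4.69% (2.96 to 7.02) of transferred cells in the IRF4 arm and 4.57% (3.69 to 5.598) in the control arm had an Irf4 UMI. Without thinning the shares were 32.6% (28.4 to 37.1) and 30.1% (28.1 to 32.2). The thinned share was 1% (0.5002 to 1.78) in monocyte or macrophage-like cells of the endogenous IRF4 library and 0.751% (0.401 to 1.28) in those of the control library, at median depths of 12049 and 16463.5 UMIs. B-like cells, a class that also uses Irf4, had thinned shares of 6.15% (2.69 to 11.8) and 3.98% (2.48 to 6.02), at median depths of 3401 and 3668 UMIs. The transferred cells had median depths of 15306 and 18501 UMIs. The log2 ratio of Irf4 was 0.90 within cluster 4, which held the largest share of both transferred libraries, and -0.70 in cells without proliferation UMIs. A 3' tag of the mouse gene can miss a vector transcript that ends in other sequence, so this value does not check which library received IRF4.

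Transferred CD8 T-like cells of the IRF4 arm had more RNA of granzyme B and proliferation genes than those of the control arm. Stem and memory genes and several cytokines were lower, and inhibitory receptor and exhaustion genes went both ways. Gzmb, which encodes granzyme B, stood at 821 against 355 CPM, ratio 2.31 (2.26 to 2.37). Havcr2, the gene of the inhibitory receptor TIM-3, stood at 32.7 against 10.1 CPM, ratio 3.25 (2.84 to 3.71), and Lag3, another inhibitory receptor, at 364 against 168 CPM, ratio 2.17 (2.09 to 2.25). Tcf7, the gene of TCF1, a transcription factor of stem-like and memory T cells, stood at 84.8 against 167 CPM, ratio 0.506 (0.474 to 0.5401). Prdm1, the gene of the effector regulator Blimp-1, was at 17.2 against 2.58 CPM, ratio 6.66 (5.34 to 8.33), and Ikzf2, the gene of Helios, at 45.3 against 265 CPM, ratio 0.171 (0.157 to 0.186). Among the other genes fixed beforehand, ratios were 1.6004 (1.54 to 1.66) for the cycle marker Mki67, 0.637 (0.588 to 0.688) for the exhaustion regulator Tox, 0.618 (0.593 to 0.643) for interferon-gamma, 0.795 (0.754 to 0.838) for the interleukin-7 receptor and 0.966 (0.928 to 1.005) for Pdcd1, the gene of PD-1. Gzmb lies at chromosome 14, 56258838 to 56262260, minus strand (ENSMUSG00000015437), Havcr2 at chromosome 11, 46454935 to 46481255, plus strand (ENSMUSG00000020399), Lag3 at chromosome 6, 124904361 to 124911705, minus strand (ENSMUSG00000030124) and Tcf7 at chromosome 11, 52252371 to 52283014, minus strand (ENSMUSG00000000782).

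Of the proliferation list, 13 of 21 members were higher (range 2 to 17) and 0 lower, with a median of 0.66 (percentile 100, range 0.26 to 0.75). Rrm2, Aurkb, Nusap1 and Birc5 had ratios of 1.84, 1.802, 1.73 and 1.71. Of the stem and memory list, 0 of 15 members were higher and 5 lower, with a median of -0.39 (percentile 0, range -0.49 to -0.20). The lower members included Lef1 (26.1 against 65.1 CPM, ratio 0.401), Id3 (0.532) and Slamf6 (0.559). Of the cytokine and chemokine list, 1 of 14 members were higher and 6 lower (range 2 to 8), with a median of -0.37 (percentile 0, range -0.67 to 0.80), with ratios of 0.112 (0.0807 to 0.151) for Csf2, 0.226 for Ccl9 and 0.282 for Il2, while Ccl5 was higher (1689.8 against 772 CPM, ratio 2.19). Of the cytotoxic list, 3 of 13 members were higher (range 1 to 6) and 0 lower, with a median of 0.037 (percentile 50.8, range -0.086 to 0.45). Gzmk (2.78) and Fasl (1.58) were higher beside Gzmb, and Gzmc had a ratio of 0.772. In the library with the higher level, 4 cells held 50% of the UMIs of Gzmc, 9 those of Il2 and 6 those of Batf3. Of the inhibitory receptor and exhaustion list, 4 of 12 members were higher and 3 lower, with a median of -0.051 (percentile 6.1, range -0.10 to 0.20), with Eomes, a T-box factor, among the lower (0.295). Of the list of IRF4 partners and targets, 3 of 12 members were higher (range 2 to 5) and 0 lower, with a median of 0.25 (percentile 99.7, range 0.045 to 0.46), led by Prdm1, Batf3 (3.398) and Ctla4 (2.16). Of the glycolysis list, 1 of 18 members were higher (range 0 to 5) and 0 lower, with a median of 0.34 (percentile 100, range 0.13 to 0.39), with Hk2, Slc16a3 and Tpi1 at 1.54, 1.47 and 1.401.

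The terminal effector list had 1 higher (range 1 to 3) and 1 lower of 9 (median -0.10, percentile 8.67, range -0.20 to 0.37). The tissue residency list had 0 higher and 1 lower of 5 (median 0.20, percentile 92.5, range -0.27 to 0.37). The TCR early activation list had 2 higher (range 2 to 6) and 2 lower of 13 (median 0.19, percentile 99.1, range 0.14 to 0.46). The costimulation and cytokine receptors list had 1 higher (range 1 to 4) and 0 lower of 14 (median 0.058, percentile 59.1, range 0.020 to 0.34). The chemokine receptors and adhesion list had 1 higher and 3 lower (range 0 to 3) of 14 (median 0.17, percentile 98.1, range -0.12 to 0.45). The respiratory chain list had 0 higher and 0 lower of 23 (median 0.13, percentile 94.8, range -0.062 to 0.15). The biosynthesis and Myc list had 0 higher and 2 lower (range 0 to 9) of 16 (median -0.074, percentile 2.15, range -0.64 to 0.037). The type I interferon response list had 2 higher and 2 lower of 7 (median -0.16, percentile 9.02, range -0.79 to -0.042). The interferon-gamma response list had 0 higher (range 0 to 3) and 0 lower of 17 (median 0.061, percentile 73.1, range 0.022 to 0.35). The unfolded protein response list had 1 higher and 0 lower of 12 (median 0.22, percentile 99.6, range 0.14 to 0.31). The apoptosis regulators list had 1 higher and 2 lower of 13 (median -0.019, percentile 23.4, range -0.058 to 0.14). The heat shock and handling stress list had 0 higher and 1 lower of 9 (median -0.026, percentile 23.8, range -0.29 to 0.073). Members of these lists included the immediate early genes Fosb (1.94) and Fos (1.83), the integrin Itgb1 (1.73), Il12rb2 (1.75), Xbp1 (1.61), the death receptor Fas (0.435), the survival gene Bcl2 (0.572), Myc (0.652) and the interferon-stimulated gene Ifi27l2a (2.11). Ranked over genes at 50 CPM or more, the highest ratios belonged to S100a6, a calcium-binding protein (2.69), the histone genes Hist1h2an (2.74), Hist1h4d (2.53), Hist1h1b (2.37) and Hist1h2ap (2.28), and the metallothionein Mt1 (2.47). Gzmb, Atp5k (2.28), Igfbp7 (2.28) and Ctla2a (2.26) completed the 10. The lowest were Ikzf2, Bmyc (0.233), Lef1, Itm2a (0.4104), Atp8b4 (0.431), Emb (0.435), Rasgrp1, which links the T cell receptor to Ras (0.442), Lad1 (0.482), Trim12a (0.498) and Tcf7.

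After thinning to 2000 UMIs, a Gzmb UMI was present in 45.6% (41.1 to 50.3) of transferred cells in the IRF4 arm and 19.4% (17.7 to 21.3) in the control arm. The corresponding shares were 55.2% (50.6 to 59.8) and 27.9% (25.9 to 29.95) for Lag3, 7.46% (5.25 to 10.2) and 1.75% (1.21 to 2.43) for Havcr2, and 14.5% (11.4 to 18.02) and 28.3% (26.3 to 30.3) for Tcf7. Unthinned, they were 69.7% and 40.1% for Gzmb, 93.4% and 79.4% for Lag3, 25.6% and 10.1% for Havcr2, and 49.3% and 75.7% for Tcf7. B-like cells of the endogenous IRF4 and control libraries, at median depths of 3401 and 3668 UMIs, had thinned shares of 7.69% and 4.36% for Gzmb, 0.769% and 0.947% for Lag3, 0% (0 of 130 cells, which allows up to 2.31%) and 0.189% for Havcr2, and 2.31% and 1.33% for Tcf7. A UMI of any of the cycle genes Mki67, Top2a, Birc5, Cdk1 and Ccnb2 was present in 38.6% (34.2 to 43.2) and 30.6% (28.5 to 32.7) of thinned transferred cells, in 68.4% and 62.5% without thinning, and in 6.15% (2.69 to 11.8) and 3.03% (1.74 to 4.87) of thinned B-like cells. Thinning left out 0 and 8 transferred cells. Ifng was present in 18.3% and 14.1% of thinned cells, an order opposite to that of its CPM, so no direction of Ifng was settled.

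The transferred cells of the IRF4 and control arms fell 34.3% and 41.3% into cluster 4, 24.3% and 19.5% into cluster 6, 19.4% and 2.46% into cluster 1, and 10.9% and 18.8% into cluster 0. Cluster 2, whose leading genes include Xcl1, Ifng, Ccl4, Il2, Ccl1, Lta and Ccl3, held 6.4% and 15.6%. Whether the lower cytokine RNA reflects the smaller share of this cluster was not tested. Beside the gene lists, the myeloid transcripts Lyz2 and Cd74 were lower in the IRF4 arm (17.9 against 38.5 CPM and 152 against 274 CPM), as was the haemoglobin gene Hbb-bs (0.0826 against 58.9 CPM). Failing the mitochondrial limit were 18.7% of barcodes in the IRF4 library and 27.2% in the control library. Within cluster 4, 2 proliferation members were higher, with 5 cytotoxic members higher. The cytokine median turned to 0.80 and the Ifng log2 ratio to 0.80 within cluster 4, and the inhibitory median lay above 0 under several alternatives, at 0.20 in that cluster.

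**Figure D1:**
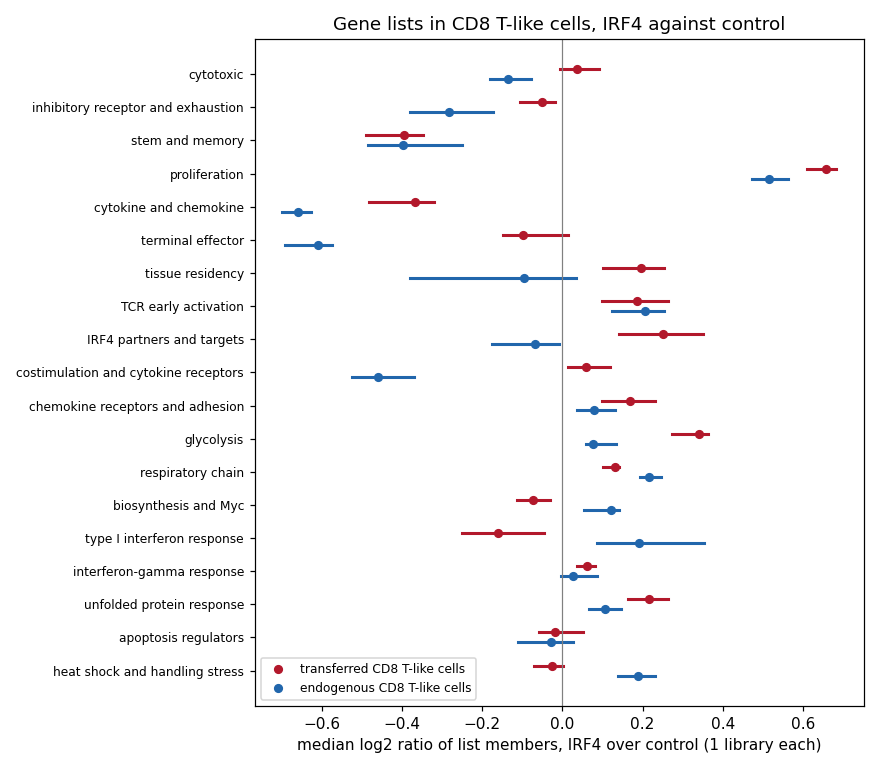
Median log2 ratio (IRF4 arm over control arm) of 19 gene lists in transferred (red) and endogenous (blue) CD8 T-like cells, with bars for counting error only. The proliferation median lies at 0.66 and 0.51, and the stem and memory median at -0.39 and -0.40.

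Among endogenous CD45+ cells, CD8 T-like, NK-like and Treg-like cells took larger shares in the IRF4 arm, and B-like, monocyte or macrophage-like, dendritic-like and neutrophil-like cells smaller ones. CD8 T-like cells made up 29.6% against 9.58% of kept cells, a ratio of 3.09 (2.81 to 3.41). NK-like cells made up 17.8% against 10.3%, a ratio of 1.73 (1.56 to 1.92), and Treg-like cells 2.51% against 1.46%, a ratio of 1.72 (1.31 to 2.27). B-like cells made up 2.06% against 9.36% (0.2198 (0.1802 to 0.267)) and monocyte or macrophage-like cells 17.4% against 30.7% (0.566 (0.524 to 0.6104)). CD4 T-like cells had a ratio of 2.201 (1.84 to 2.65), but their log2 ratio was -0.010 at Leiden resolution 0.5 and -0.032 under an earlier naming rule, so their direction was not settled.

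Ratios of shares were 0.649 (0.486 to 0.865) for cDC1-like cells, which cross-present antigen, 0.614 (0.5205 to 0.722) for cDC2-like cells, 0.613 (0.451 to 0.8303) for mature dendritic-like cells, 0.448 (0.342 to 0.584) for plasmacytoid dendritic-like cells, 0.436 (0.298 to 0.629) for neutrophil-like cells and 0.891 (0.576 to 1.38) for mast or basophil-like cells. Unnamed clusters held 14.7% and 19.4% of cells in the IRF4 and control libraries. Among them were cluster 17, led by Klra6 and Tcrg-C1, with 617 and 331 cells, and cluster 10, led by Inhba and Nos2, with 210 and 453 cells. The sort gate can set all of these shares, and the shares of 1 library sum to a fixed total, so a larger class makes the others smaller.

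**Figure D2:**
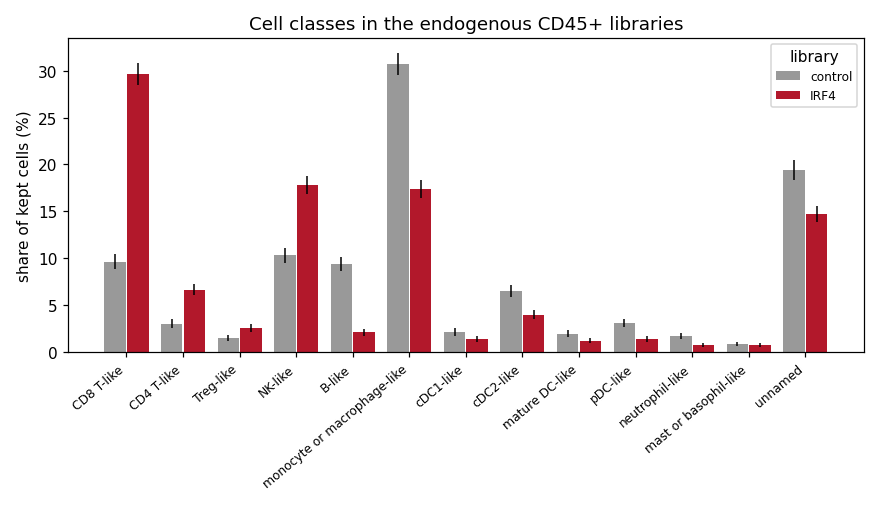
Share of kept endogenous cells (percent) in 12 named classes and in unnamed clusters, control arm in grey and IRF4 arm in red, with exact binomial intervals. CD8 T-like cells stand at 29.6% in the IRF4 arm and 9.58% in the control arm.

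Endogenous CD8 T-like cells had more RNA of Gzmk, Klrg1 and proliferation genes in the IRF4 arm, and less of several costimulatory receptors. Several cytokines were also lower, some resting on few control cells. Gzmk, the gene of granzyme K, stood at 421 against 155 CPM, ratio 2.72 (2.57 to 2.88), and Klrg1, a receptor of differentiated effector cells, at 49.98 against 12.6 CPM, ratio 3.97 (3.25 to 4.9002). Tnfrsf9, the gene of the costimulatory receptor 4-1BB, stood at 169.8 against 333 CPM, ratio 0.5103 (0.487 to 0.534). Ifng stood at 159 against 261 CPM, ratio 0.6098 (0.5797 to 0.642), but it turned in cells without proliferation UMIs and was not settled. Ratios of the other primary genes were 1.27 (1.22 to 1.33) for Pdcd1, 0.721 (0.684 to 0.761) for Lag3, 0.729 (0.6805 to 0.782) for Havcr2, 1.12 (1.06 to 1.19) for Tox and 0.7095 (0.642 to 0.786) for Tcf7. They were 1.11 (1.08 to 1.13) for Gzmb, 1.25 (1.197 to 1.297) for Mki67, 0.821 (0.7502 to 0.899) for Il7r and 1.01 (0.7998 to 1.296) for Irf4.

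Of the proliferation list, 7 of 21 members were higher (range 1 to 16) and 0 lower, with a median of 0.51 (percentile 100, range 0.29 to 0.78), with Hmgb2 (1.797), Rrm2 (1.78), Stmn1 (1.66) and Aurkb (1.63) among the higher. Of the cytokine and chemokine list, 0 of 14 members were higher and 9 lower (range 3 to 10), with a median of -0.66 (percentile 0, range -1.13 to -0.016), with Csf2 at 0.323, Ccl3 at 0.438 and Ccl9 at 0.334. Ccl1 was lowest (13.6 against 248 CPM, ratio 0.054999), but 4 cells in each library held 50% of its UMIs. In the control arm 50% of the UMIs lay in 9 cells for Ifng, 9 for Ccl3, 4 for Ccl9, 2 for Csf2 and 4 for Ccr7. Of the terminal effector list, 1 of 10 members were higher and 5 lower (range 0 to 6), with a median of -0.61 (percentile 0, range -0.93 to -0.071), with Cx3cr1 (0.448), Zeb2 (0.487) and Klre1 (0.5505) lower beside the higher Klrg1. Of the list of costimulation and cytokine receptors, 0 of 15 members were higher and 6 lower (range 3 to 7), with a median of -0.46 (percentile 0, range -0.55 to -0.086), with Il2ra (0.483), Il18rap (0.547) and Tnfrsf4 (0.588). The cytokine, terminal effector and costimulation medians came nearest to 0 in cells without proliferation UMIs. Of the inhibitory receptor and exhaustion list, 3 of 16 members were higher and 4 lower (range 3 to 7), with a median of -0.28 (percentile 0, range -0.36 to 0.16), with Tox2 (2.898) and Eomes (1.94) higher and Cd244 (0.402) lower. Of the stem and memory list, 0 of 15 members were higher and 4 lower (range 0 to 5), with a median of -0.40 (percentile 0, range -0.53 to 0.17), with Ccr7 (0.404), Bach2 (0.424), Id3 (0.536) and Ly6c2 (0.662). Of the cytotoxic list, 2 of 17 members were higher and 7 lower (range 4 to 8), with a median of -0.14 (percentile 0.29, range -0.40 to -0.084). Gzmf (0.325) and Gzme (0.415) were lower, but 2 and 2 control cells held 50% of their UMIs, 4 and 1 in the IRF4 arm. Without the cell of each library richest in granzymes the cytotoxic median was -0.40. The higher ratio of Gzmg (11.8) rested on 1 cell that held 625 of 628 UMIs.

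The tissue residency list had 0 higher and 3 lower (range 1 to 4) of 7 (median -0.10, percentile 21.2, range -0.50 to 0.092). The TCR early activation list had 3 higher (range 2 to 7) and 1 lower of 12 (median 0.20, percentile 99.7, range 0.050 to 0.70). The IRF4 partners and targets list had 3 higher (range 1 to 5) and 3 lower of 12 (median -0.069, percentile 11.7, range -0.14 to 0.094). The chemokine receptors and adhesion list had 1 higher and 2 lower (range 0 to 3) of 14 (median 0.079, percentile 71.9, range 0.012 to 0.50). The glycolysis list had 0 higher and 1 lower of 17 (median 0.077, percentile 75.01, range -0.10 to 0.13). The respiratory chain list had 0 higher and 0 lower of 23 (median 0.22, percentile 99.8, range 0.027 to 0.23). The biosynthesis and Myc list had 0 higher and 0 lower of 15 (median 0.12, percentile 88.9, range -0.24 to 0.16). The type I interferon response list had 1 higher (range 1 to 12) and 0 lower of 14 (median 0.19, percentile 99.5, range 0.084 to 1.06). The interferon-gamma response list had 1 higher (range 1 to 6) and 1 lower of 19 (median 0.026, percentile 39.1, range -0.025 to 0.35). The unfolded protein response list had 0 higher and 0 lower of 12 (median 0.11, percentile 82.6, range -0.11 to 0.16). The apoptosis regulators list had 0 higher and 2 lower of 12 (median -0.029, percentile 16.9, range -0.094 to 0.044). The heat shock and handling stress list had 1 higher (range 0 to 5) and 0 lower of 9 (median 0.19, percentile 95.4, range 0.065 to 0.55). Single members included the integrins Itgae (0.168) and Itga1 (0.301), which hold T cells in tissue, the immediate early genes Fos (2.01), Dusp1 (1.86) and, in the other direction, Nr4a3 (0.423), the transcription factors Maf (2.81) and Irf8 (0.4697), Cxcr4 (2.28), Isg15 (1.83) and the pro-apoptotic Bcl2l11 (0.478). In the ranking, Gzmk, Pmm1 (2.37), Mt1 (2.11), BC021614 (2.099) and Fos were highest, and Ccl1, Car2 (0.251), Serpinb9b (0.284), Gzmf and Actn1 (0.343) lowest, with 50% of the Serpinb9b UMIs of the control arm in 5 cells.

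Thinned to 2000 UMIs, 54.7% (52.4 to 56.9) of these cells in the IRF4 arm and 44.1% (39.9 to 48.4) in the control arm had a Gzmb UMI, and 42.2% (39.96 to 44.5) and 31.6% (27.7 to 35.7) a Pdcd1 UMI. Unthinned shares were 75.4% and 61.8% for Gzmb and 71.98% and 62.9% for Pdcd1, at median depths of 11420.5 and 9160.5 UMIs. Thinned B-like cells of the same libraries, at median depths of 3401 and 3668 UMIs, had shares of 7.69% and 4.36% for Gzmb and 2.31% and 1.52% for Pdcd1. A UMI of any of the 5 cycle genes named above was present in 44.1% (41.8 to 46.3) and 31.4% (27.6 to 35.5) of thinned endogenous CD8 T-like cells, against the B-like shares given for transferred cells, and in 61.9% and 50.4% without thinning. Thinning left out 2 and 0 of these cells. Clusters 1, 0 and 11 held 31.5%, 29.1% and 28.02% of the class in the IRF4 arm and 24.6%, 50.2% and 15.3% in the control arm. The haemoglobin transcript Hbb-bs stood at 0.301 against 687 CPM beside these lists, Lyz2 at 39.1 against 68.6 CPM and Cd74 at 65.5 against 122 CPM. Over cells without proliferation UMIs the inhibitory median turned to 0.16 and the Ifng log2 ratio to 0.89. Within clusters 1 and 11 the stem and memory median turned to 0.050 and the Gzmb log2 ratio to -0.053, and under the first naming rule the Tcf7 log2 ratio turned to 0.62.

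Monocyte or macrophage-like cells of the IRF4 arm had more RNA of interferon-stimulated and early activation genes, and less of genes linked to suppressive or repair macrophages. Cxcl9 and Cxcl10, chemokines that draw CXCR3-bearing T cells, stood at 772 against 313 CPM, ratio 2.47 (2.41 to 2.53) and at 869 against 314 CPM, ratio 2.76 (2.69 to 2.83). The interferon-stimulated genes Isg15 and Mx1 had ratios of 2.76 (2.65 to 2.89) and 2.997 (2.72 to 3.303). Mrc1, the mannose receptor, stood at 70.7 against 415 CPM, ratio 0.1705 (0.1603 to 0.181), and Spp1, the gene of osteopontin, at 497 against 2108 CPM, ratio 0.236 (0.2303 to 0.241). The class held 1106 cells in the IRF4 arm and 1742 in the control arm.

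Of the type I interferon list, 17 of 18 members were higher (range 2 to 17) and 0 lower, with a median of 1.05 (percentile 100, range 0.18 to 1.07), with Ifit3b and Ifit3 at 3.03 and 2.62. Of the interferon-gamma list, 12 of 20 members were higher (range 0 to 14) and 0 lower, with a median of 0.67 (percentile 100, range -0.16 to 0.73), with the GTPases Gbp5 and Gbp2 at 2.44 and 2.31. Of the suppressive or repair list, 1 of 12 members were higher and 7 lower (range 1 to 10), with a median of -1.07 (percentile 0, range -1.39 to -0.027), with the folate receptor Folr2 at 0.132 and the elastase Mmp12 at 0.246. Of the proliferation list, 0 of 21 members were higher and 19 lower (range 0 to 19), with a median of -0.92 (percentile 0, range -1.17 to 0.11), with Cenpf, Nusap1 and Top2a at 0.331, 0.4002 and 0.463. Of the inflammatory list, 2 of 10 members were higher (range 2 to 5) and 1 lower, with a median of 0.27 (percentile 99.3, range 0.068 to 0.59), with the costimulatory Cd40 (2.07) and Tnf (1.96) higher and the monocyte chemokine Ccl2 (0.564) lower. The MHC class II list had 0 higher and 0 lower of 8 (median -0.22, percentile 2.52, range -0.49 to 0.18). The glycolysis list had 0 higher (range 0 to 6) and 0 lower of 17 (median -0.38, percentile 0, range -0.51 to 0.53). The respiratory chain list had 0 higher and 0 lower of 23 (median -0.086, percentile 8.95, range -0.10 to 0.15). The biosynthesis and Myc list had 0 higher and 3 lower (range 0 to 5) of 14 (median -0.40, percentile 0, range -0.57 to 0.073). The unfolded protein response list had 0 higher and 1 lower of 12 (median -0.16, percentile 4.39, range -0.23 to 0.080). The apoptosis regulators list had 1 higher and 2 lower (range 0 to 3) of 13 (median 0.12, percentile 94.3, range -0.17 to 0.19). The heat shock and handling stress list had 2 higher (range 1 to 4) and 0 lower of 10 (median 0.37, percentile 99.8, range 0.039 to 0.50). The T cell early activation list overlaps the ranking and was run after seeing it, under no alternative. It had 9 higher and 0 lower of 12 (median 1.03, percentile 100). Members of these included H2-Aa (0.742), Gapdh (0.707), Nolc1 (0.559), Fas (2.28) and Hspa1a (1.91). In the ranking, Fosb (4.08), Dusp1 (3.92), Fos (3.46), Dusp2 (3.25) and Egr1 (3.01) were highest, and the neutrophil chemokine Cxcl3 (0.149), Mrc1, Pf4 (0.1799), Stab1 (0.209) and Spp1 lowest. Primary genes had ratios of 1.06 for Irf4, 0.439 for Mki67, 0.7695 for Havcr2, 0.513 for Lag3, 1.24 for Pdcd1 and 0.926 for Tox. They were 1.15 for Tcf7, 0.765 for Il7r, 1.29 for Gzmb and 0.811 for Ifng, with Tcf7 and Ifng at low levels. For Cxcl3 and Ifng, 10 and 8 control cells held 50% of the UMIs, and for Gzmb 9 cells of the IRF4 arm.

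Different clusters held most of this class in the 2 arms, with cluster 7, led by Ccl7 and Vcan, at 28.3% in the IRF4 arm and 56.3% in the control arm, and cluster 14, led by Ace and Adgre4, at 45.2% and 24.5%. Cluster 8, led by Cxcl10 and Cxcl9, held 22.3% and 8.09%, and cluster 9, led by Gas6 and Vcam1, 4.16% and 11.1%. The haemoglobin gene Hbb-bs stood at 1.2002 against 526 CPM beside these lists. Cluster by cluster, the interferon-gamma median was 0.73, -0.028, 0.51 and -0.16 in clusters 7, 8, 9 and 14, and Mrc1 and Spp1 turned to log2 ratios of 0.26 and 0.79 in cluster 14. The proliferation median turned to 0.070, 0.11 and 0.023 in clusters 7, 8 and 9, and the Mki67 log2 ratio to 0.12 when cells were clustered again with marked doublets kept, so no direction of proliferation was settled in this class. The MHC class II and smaller lists also turned in some clusters, as did Pdcd1, Gzmb, Lag3, Il7r and Ifng under some alternatives, and Cxcl3 and Havcr2 in cluster 9.

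**Figure D3:**
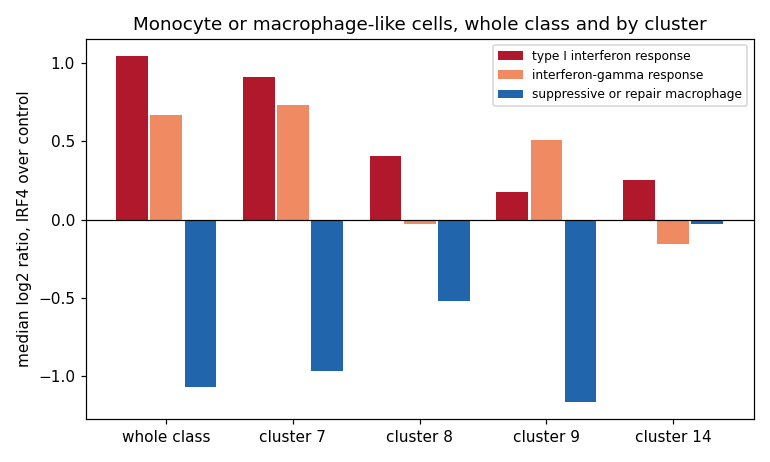
Median log2 ratio (IRF4 arm over control arm) of 3 gene lists in all monocyte or macrophage-like cells and in each of their 4 clusters, as bars without error bars. The type I interferon bars read 1.05 for the class and 0.91, 0.41, 0.18 and 0.25 for clusters 7, 8, 9 and 14, and the suppressive bars -1.07, -0.97, -0.52, -1.17 and -0.027.

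In NK-like cells few members of the lists fixed for this class differed by 1.5 times, and the top genes included several immediate early genes. The T cell early activation list had 6 of 12 members higher and 1 lower (median 0.52, percentile 100). Run under no alternative after the ranking was seen, it holds Dusp1 and Egr1 and cannot check them. The phosphatase gene Dusp1 stood at 374 against 133 CPM, ratio 2.82 (2.54 to 3.13), Klf4 at a ratio of 2.75 (2.18 to 3.495), the cytokine signal suppressor Socs3 at 2.43 (2.04 to 2.91), Egr1 at 2.15 (1.899 to 2.44) and Erdr1 at 2.11 (1.79 to 2.4997). Isg15 had a ratio of 1.79 (1.26 to 2.58) and Gzmb one of 1.02 (0.9799 to 1.07). The class held 1134 cells in the IRF4 arm and 584 in the control arm.

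Of the type I interferon list, 2 of 9 members were higher (range 1 to 13) and 0 lower, with a median of 0.32 (percentile 100, range 0.18 to 0.92), with Isg15 and Ifi27l2a (1.63) higher. Of the interferon-gamma list, 1 of 19 members were higher (range 0 to 4) and 0 lower, with a median of 0.14 (percentile 99.98, range 0.13 to 0.25), with Iigp1 at 1.78. Of the NK maturation list, 0 of 12 members were higher and 1 lower, with a median of -0.11 (percentile 4.51, range -0.18 to -0.094), with S1pr5, an egress receptor, at 0.6101 and Zeb2 at 0.707. Of the cytotoxic list, 0 of 17 members were higher and 4 lower (range 0 to 5), with a median of -0.057 (percentile 4, range -0.091 to 0.041), and -0.057 with the member at 0 UMIs set at its bound. The 4 lower members rested on single cells: Gzmg had 2004 UMIs in the control arm, all in 1 cell, and 0 in the IRF4 arm, at least 1361-fold lower against a floor of 3 counts. For Gzmf (ratio 0.000635 (0.000131 to 0.00186)), Gzmd (0.0918) and Gzme (0.3499), 1 control cell held 2316 of 2320, 2101 of 2128 and 295 of 296 UMIs, and Mt1 (0.131) had 187 of 217 in 1 cell. Without the richest granzyme cell of each library, 0 cytotoxic members were lower and the Havcr2 log2 ratio turned to 1.13. The proliferation list had 0 higher (range 0 to 7) and 0 lower of 9 (median 0.33, percentile 100, range 0.15 to 0.50). The glycolysis list had 0 higher and 0 lower of 17 (median 0.10, percentile 99.6, range 0.040 to 0.16). The respiratory chain list had 0 higher and 0 lower of 23 (median 0.062, percentile 97.8, range 0.012 to 0.082). The biosynthesis and Myc list had 0 higher and 0 lower of 14 (median 0.066, percentile 96.2, range -0.0078 to 0.17). The unfolded protein response list had 0 higher and 0 lower of 12 (median 0.11, percentile 99.5, range 0.076 to 0.15). The apoptosis regulators list had 0 higher and 0 lower of 12 (median 0.077, percentile 96.7, range 0.062 to 0.13). The heat shock and handling stress list had 0 higher and 0 lower of 9 (median 0.22, percentile 99.98, range 0.15 to 0.28). Other primary genes had ratios of 1.02 for Tcf7, 1.03 for Tox, 0.952 for Il7r, 1.35 for Ifng, 1.16 for Mki67, 1.15 for Lag3 and 1.66 for Pdcd1, while Havcr2 (0.439 (0.214 to 0.892)) and Irf4 (2.45 (0.523 to 23.04)) had few UMIs. The haemoglobin gene Hbb-bs was higher here in the IRF4 arm, at 149 against 75.9 CPM, and how many cells held its UMIs was not examined. Treg-like cells, with 83 cells in the control arm and 160 in the IRF4 arm, missed the minimum of 100 cells for list comparisons.

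Transferred cells differed from endogenous CD8 T-like cells of the same tumours in both arms, with more RNA of stem and memory genes and less of granzymes and interferon-stimulated genes. In the control arm Dapl1, a gene of less differentiated T cells, stood at 486 against 30.4 CPM, ratio 16.01 (14.1 to 18.2), and Tcf7 at 167 against 63.9 CPM, ratio 2.62 (2.398 to 2.87). In the IRF4 arm Ccr7, the lymph node homing receptor, stood at 259 against 16.5 CPM, ratio 15.7 (14.3 to 17.2), and Tcf7 at 84.8 against 45.3 CPM, ratio 1.87 (1.73 to 2.03). Irf4 was higher in transferred cells of both arms, with ratios of 2.32 (1.87 to 2.92) in the control arm and 2.58 (2.21 to 2.995) in the IRF4 arm. Havcr2 was lower in both, at 0.0751 (0.0675 to 0.0834) and 0.334 (0.3005 to 0.371), and Lag3 had ratios of 0.738 (0.702 to 0.777) and 2.22 (2.13 to 2.31). The control arm comparison was between 1954 transferred and 544 endogenous cells, and the IRF4 arm comparison between 469 and 1888.

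In the control arm, of the cytotoxic list, 0 of 16 members were higher and 12 lower, with a median of -1.59 (percentile 0, range -2.25 to -1.22), with ratios of 0.0118 for Gzmd, 0.0326 for Gzmf, 0.0273 for Gzme, 0.0514 for Gzmk and 0.3299 for Gzmb. In endogenous control cells, 2 cells held 50% of the UMIs of Gzmd, 1 of them 298 of 811, and 2 and 2 cells those of Gzmf and Gzme. Of the stem and memory list, 10 of 15 members were higher and 3 lower, with a median of 1.23 (percentile 100, range 0.88 to 2.41), with Id3 (6.18), Ccr7 (5.08) and Bach2 (3.86) higher. Of the type I interferon list, 0 of 13 members were higher and 11 lower (range 3 to 14), with a median of -1.38 (percentile 0, range -1.45 to -0.41), with Rtp4 (0.185) and Ifit1 (0.192). Of the inhibitory receptor and exhaustion list, 2 of 15 members were higher and 7 lower, with a median of -0.47 (percentile 0.03, range -0.82 to -0.019), with the ectoenzymes Entpd1 (0.0926) and Cd38 (0.144) lower. Of the terminal effector list, 0 of 10 members were higher and 7 lower (range 4 to 7), with a median of -0.99 (percentile 0, range -1.101 to -0.43), with Prdm1 (0.0909), Klrg1 (0.118) and Id2 (0.191) lower. Of the cytokine and chemokine list, 6 of 15 members were higher (range 2 to 8) and 3 lower, with a median of 0.094 (percentile 87.2, range -0.83 to 0.91), with Xcl1 (5.66) higher and Ccl5 (0.112) lower. The proliferation list had 0 higher and 12 lower (range 5 to 18) of 21 (median -0.65, percentile 0, range -1.097 to -0.37). The tissue residency list had 0 higher and 3 lower (range 1 to 3) of 7 (median -0.33, percentile 10.2, range -0.37 to -0.27). The TCR early activation list had 5 higher (range 2 to 5) and 4 lower of 13 (median -0.27, percentile 7.9, range -0.32 to -0.10). The IRF4 partners and targets list had 0 higher and 5 lower (range 3 to 6) of 12 (median -0.32, percentile 4.7, range -0.51 to -0.15). The costimulation and cytokine receptors list had 2 higher and 3 lower (range 3 to 5) of 15 (median -0.19, percentile 14.5, range -0.21 to -0.023). The chemokine receptors and adhesion list had 3 higher and 8 lower (range 3 to 8) of 14 (median -0.80, percentile 0, range -0.84 to -0.12). The glycolysis list had 2 higher (range 0 to 5) and 1 lower of 18 (median -0.026, percentile 62.2, range -0.40 to 0.12). The respiratory chain list had 1 higher and 0 lower of 23 (median 0.066, percentile 83.9, range -0.18 to 0.13). The biosynthesis and Myc list had 6 higher (range 1 to 9) and 0 lower of 16 (median 0.47, percentile 100, range 0.010 to 0.69). The interferon-gamma response list had 0 higher and 11 lower (range 3 to 11) of 19 (median -0.65, percentile 0, range -0.74 to -0.41). The unfolded protein response list had 0 higher and 0 lower of 12 (median 0.15, percentile 96.03, range -0.39 to 0.36). The apoptosis regulators list had 3 higher and 2 lower of 13 (median 0.035, percentile 86.3, range -0.16 to 0.21). The heat shock and handling stress list had 2 higher and 2 lower of 9 (median -0.0024, percentile 64.2, range -0.18 to 0.058). In the ranking Cd81 (18.8), Dapl1, Spry1 (20.5), Rgcc (9.26) and Marcksl1 (8.68) were highest, and Gzmd, Gzmf, Gzme, Gzmk and Serpinb9b (0.04496) lowest, where 5 endogenous cells held 50% of the Serpinb9b UMIs and 10 those of Klrg1. Further ratios were 0.843 for Pdcd1, 0.536 for Tox, 2.22 for Il7r, 1.38 for Ifng and 0.577 for Mki67.

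In the IRF4 arm, of the cytotoxic list, 0 of 17 members were higher and 10 lower, with a median of -1.097 (percentile 0, range -1.15 to -0.62), and -1.097 with members at 0 UMIs set at their bounds. Gzmd, Gzme and Gzmg had 0 UMIs in transferred cells and were at least 439.5-fold, 121-fold and 76.3-fold lower against a floor of 3 counts, Gzmf had a ratio of 0.00341 (0.000702 to 0.00997), and Gzmb one of 0.68999. In endogenous cells of this arm, 1 cell held 3373 of 3616 Gzmd UMIs, 632 of 995 Gzme UMIs and 625 of 628 Gzmg UMIs, and 4 cells held 50% of those of Gzmf. Of the stem and memory list, 9 of 15 members were higher and 3 lower, with a median of 0.99 (percentile 100, range 0.38 to 1.501), with Dapl1 (8.71), Bach2 (7.299) and Id3 (6.12). Of the type I interferon list, 1 of 14 members were higher and 12 lower, with a median of -2.21 (percentile 0, range -2.95 to -1.68), with Ifit1 (0.0289) and Ifit3 (0.0381). Of the inhibitory receptor and exhaustion list, 5 of 16 members were higher and 9 lower, with a median of -1.08 (percentile 0, range -1.14 to -0.39), with Eomes (0.02901) lower and Cd200 (4.35) higher. Of the list of costimulation and cytokine receptors, 5 of 15 members were higher and 2 lower, with a median of 0.38 (percentile 100, range 0.30 to 0.51), with Il2ra (5.71) and Tnfrsf4 (4.14). Of the list of IRF4 partners and targets, 5 of 13 members were higher (range 2 to 5) and 5 lower, with a median of -0.042 (percentile 59.1, range -0.092 to 0.030), with Batf3 (5.17) higher and Batf (0.391) and Maf (0.186) lower. The proliferation list had 0 higher and 7 lower (range 1 to 18) of 21 (median -0.50, percentile 0, range -1.15 to -0.43). The cytokine and chemokine list had 3 higher and 3 lower of 14 (median 0.020, percentile 79.7, range -0.42 to 0.37). The terminal effector list had 2 higher and 5 lower (range 3 to 5) of 10 (median -0.47, percentile 0.26, range -0.41 to -0.28). The tissue residency list had 0 higher and 2 lower of 4 (median -0.46, percentile 3.29, range -0.46 to -0.33). The TCR early activation list had 3 higher and 5 lower (range 2 to 5) of 13 (median -0.20, percentile 13.96, range -0.30 to -0.092). The chemokine receptors and adhesion list had 3 higher and 8 lower (range 5 to 8) of 14 (median -0.73, percentile 0, range -0.67 to -0.22). The glycolysis list had 5 higher (range 2 to 7) and 0 lower of 18 (median 0.27, percentile 99.96, range 0.00026 to 0.35). The respiratory chain list had 0 higher and 0 lower of 23 (median -0.032, percentile 67.9, range -0.26 to 0.059). The biosynthesis and Myc list had 4 higher (range 0 to 4) and 0 lower of 15 (median 0.34, percentile 100, range -0.18 to 0.41). The interferon-gamma response list had 1 higher and 10 lower of 19 (median -0.60, percentile 0, range -0.79 to -0.41). The unfolded protein response list had 1 higher and 0 lower of 12 (median 0.26, percentile 99.9, range 0.15 to 0.33). The apoptosis regulators list had 3 higher and 2 lower of 13 (median 0.19, percentile 99.3, range 0.15 to 0.34). The heat shock and handling stress list had 1 higher and 2 lower (range 2 to 5) of 9 (median -0.15, percentile 25.7, range -0.51 to -0.076). In the ranking Ccl1 (34.5), Ccr7, Cd81 (12.1), Igfbp7 (11.3) and Dapl1 were highest, and Gzmd, Gzmf, Eomes, Gzmk (0.0527) and Ccr2 (0.0644) lowest. For Ccl1, 8 transferred cells held 50% of the UMIs, 1 of them 763 of 5681, and 4 endogenous cells did so. For Ifng and Batf3, 10 and 6 transferred cells held 50%. Further ratios were 0.639 for Pdcd1, 0.304 for Tox, 2.15 for Il7r, 1.398 for Ifng and 0.741 for Mki67.

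Different clusters held most cells of the transferred and endogenous libraries, as given above for each, and the libraries differed in sort gate and depth. Under the first naming rule the cytokine, respiratory chain and unfolded protein medians turned to -0.83, -0.18 and -0.39 in the control arm. That rule also moved the median log2 ratio of all genes to -0.14 in the control arm and -0.13 in the IRF4 arm, so values under it are read relative to these.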

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

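No test was run on the values of this part, and the rule that picked opposite directions was set after the values had been read. In the following cases the IRF4 arm lay above the control arm in one kind of CD8 T-like cell and below it in the other, with both intervals for counting error leaving out 0, and the differences were not tested. The log2 ratio of Havcr2 differed by 2.06 (1.61 in transferred and -0.45 in endogenous cells), that of Lag3 by 1.58 (1.11 in transferred and -0.47 in endogenous cells), and that of Tox by -0.81 (-0.64 in transferred and 0.16 in endogenous cells). The median of the costimulation and cytokine receptor list differed by 0.52 (0.058 in transferred and -0.46 in endogenous cells), and that of IRF4 partners and targets by 0.32 (0.25 in transferred and -0.069 in endogenous cells). The biosynthesis and Myc median differed by -0.19 (-0.074 in transferred and 0.12 in endogenous cells). The type I interferon median differed by -0.35 (-0.16 over 7 members in transferred and 0.19 over 14 in endogenous cells), so over different sets. The cytotoxic, tissue residency and heat shock medians also had opposite signs, but an interval of each held 0. The endogenous median of IRF4 partners and targets lay above 0 under 4 alternatives, at up to 0.094 with thinned cells. In both kinds of cell the biosynthesis and Myc median also changed sign under some alternatives.

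A signal outside the comparisons came from Xist, the X-inactivation transcript. A UMI of it was found in 40.9% of transferred CD8 T-like cells of the control arm and in 36.9% of those of the IRF4 arm. In endogenous CD8 T-like cells the shares were 0% in the control arm (0 of 544 cells, which allows up to 0.551%) and 0.05297% in the IRF4 arm. After thinning to 2000 UMIs the transferred shares were 29.3% and 28.4%. The Y-linked Ddx3y was also present in the transferred libraries, at 35.9 against 43.6 CPM in the IRF4 and control arms.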

How the results depend on the processing

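No paired analysis was possible because each group had 1 library and no test was made. In all, 3984 alternative values were computed for 318 results: 2768 stayed within counting error or within 1.5 times the count, 1125 moved otherwise and 91 changed sign from a value whose interval left out 0. Of those that moved, 57 also changed sign, from a value whose interval held 0, as did 18 of those that stayed. Of the 2339 fixed before the data were examined, 1768 stayed, 552 moved, 32 of them across 0, and 19 changed sign from a value whose interval left out 0. Of the 1645 chosen after seeing the data, 1000 stayed, 573 moved, 25 of them across 0, and 72 changed sign from a value whose interval left out 0. Of 219 log2 ratios, medians and differences of shares, 144 kept their sign under every alternative run. Cells without proliferation UMIs were picked by members of the proliferation list, so their values for that list and its genes are set by the choice itself and say nothing about it. Keeping marked doublets returned only 6 cells but led to a new clustering, so its effect is that of clustering again. The cause of the other moves below was not tested.

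The values below are log2 ratios and medians unless counts of higher or lower list members are named, under alternatives fixed before the data were examined. Without the filter on low counts, transferred cells turned to medians of -0.086 (cytotoxic), 0.19 (inhibitory) and -0.24 (residency). Without the filter on low counts, endogenous CD8 cells turned to 0.029 (IRF4 partner), and monocyte or macrophage-like cells gave -1.17 (suppressive) and 0.23 (inflammatory). With cells weighted equally, transferred cells gave medians of 0.14 (cytotoxic), -0.34 (stem) and 0.58 (proliferation). With cells weighted equally, endogenous CD8 cells gave lower counts of 4 (cytotoxic), and medians of -0.12 (inhibitory), -0.094 (stem) and 0.74 (proliferation), and higher counts of 16 (proliferation), and turned to medians of 0.00050 (IRF4 partner), and log2 ratios of 0.15 (Il7r). With cells weighted equally, NK-like cells gave lower counts of 0 (NK maturation), and turned to log2 ratios of 0.41 (Havcr2). With cells weighted equally, monocyte or macrophage-like cells gave medians of -0.30 (MHC class II), -1.39 (suppressive) and 0.11 (inflammatory). With each cell thinned to 2000 UMIs, transferred cells gave medians of 0.11 (cytotoxic), -0.22 (stem) and 0.60 (proliferation), and turned to medians of 0.13 (inhibitory). With each cell thinned to 2000 UMIs, endogenous CD8 cells gave lower counts of 4 (cytotoxic), and medians of -0.33 (cytotoxic), -0.11 (inhibitory), -0.19 (stem) and 0.78 (proliferation), and higher counts of 16 (proliferation), and turned to medians of 0.094 (IRF4 partner), and log2 ratios of 0.12 (Il7r). NK-like cells turned to log2 ratios of 0.16 (Gzme) and 1.47 (Havcr2) with each cell thinned to 2000 UMIs. With each cell thinned to 2000 UMIs, monocyte or macrophage-like cells gave medians of -0.28 (MHC class II), -1.38 (suppressive) and 0.10 (inflammatory), and turned to log2 ratios of -0.84 (Pdcd1). With each cell thinned to 2000 UMIs, transferred against endogenous cells in control tumours gave medians of -1.22 (cytotoxic), -0.019 (inhibitory), 0.88 (stem) and -0.37 (proliferation), and lower counts of 5 (proliferation). With each cell thinned to 2000 UMIs, transferred against endogenous cells in IRF4 tumours gave medians of -0.62 (cytotoxic), -0.39 (inhibitory) and 0.38 (stem). Over cells picked by their own Cd8a or Cd8b1 UMIs, transferred cells gave medians of 0.10 (cytotoxic) and 0.75 (proliferation). Over cells without proliferation UMIs, transferred cells gave medians of 0.19 (cytotoxic), -0.20 (stem) and 0.056 (proliferation), and higher counts of 0 (proliferation), and turned to medians of -0.062 (respiratory chain), and log2 ratios of -0.70 (Irf4). Over all kept cells, transferred cells gave medians of -0.32 (stem). With marked doublets kept, transferred cells gave medians of 0.69 (proliferation), and endogenous CD8 cells -0.036 (stem) and 0.47 (proliferation), turning to 0.051 (Il7r). With marked doublets kept, monocyte or macrophage-like cells gave medians of -0.49 (MHC class II) and -0.62 (suppressive), and turned to log2 ratios of 0.25 (Ifng) and 0.12 (Mki67). With marked doublets kept, class shares gave log2 ratios of -0.42 (monocyte or macrophage-like share). At 5% mitochondrial UMIs, transferred cells gave medians of 0.69 (proliferation), and endogenous CD8 cells -0.23 (stem) and 0.46 (proliferation). At Leiden resolution 0.5, transferred cells gave medians of 0.69 (proliferation), and endogenous CD8 cells -0.18 (stem). At Leiden resolution 0.5, monocyte or macrophage-like cells gave medians of -0.25 (MHC class II) and 0.068 (inflammatory). At Leiden resolution 0.5, class shares turned to log2 ratios of -0.010 (CD4 T-like share). With median-ratio scaling, endogenous CD8 cells gave medians of -0.19 (cytotoxic) and 0.46 (proliferation). With median-ratio scaling, transferred against endogenous cells gave medians of -0.41 (inhibitory) in control tumours. In IRF4 tumours this scaling gave lower counts of 1 (proliferation), and medians of -0.43 (proliferation). Differences of shares in endogenous CD8 cells turned to 1.23 percentage points without thinning (Lag3) and -1.42 with cells thinned to 1000 UMIs (Tox).

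The next values come from alternatives chosen after seeing the data. Over cells without proliferation UMIs, endogenous CD8 cells gave lower counts of 4 (cytotoxic) and 0 (stem), and medians of -0.035 (stem) and 0.34 (proliferation), and higher counts of 2 (proliferation), and turned to medians of 0.16 (inhibitory), 0.0055 (IRF4 partner), -0.057 (glycolysis) and -0.038 (Myc), and log2 ratios of -0.14 (Mt1), 0.36 (Il7r) and 0.89 (Ifng). Under naming rule 1, transferred cells gave higher counts of 6 (cytotoxic) and 4 (proliferation), and medians of 0.45 (cytotoxic) and 0.34 (proliferation), and log2 ratios of 0.90 (Irf4), and turned to medians of 0.18 (inhibitory), 0.55 (cytokine) and -0.026 (respiratory chain), and log2 ratios of 0.69 (Ifng). Under naming rule 1, endogenous CD8 cells gave medians of -0.40 (cytotoxic) and 0.35 (proliferation), and lower counts of 2 (stem), and higher counts of 4 (proliferation), and turned to medians of 0.17 (stem), -0.10 (glycolysis), -0.24 (Myc) and -0.11 (unfolded protein), and log2 ratios of -0.012 (Mt1), 0.62 (Tcf7) and -0.060 (Gzmb). Under naming rule 1, transferred against endogenous cells in control tumours gave medians of -2.25 (cytotoxic), -0.82 (inhibitory), 2.41 (stem) and -1.097 (proliferation), and turned to medians of -0.83 (cytokine), -0.18 (respiratory chain) and -0.39 (unfolded protein). Under naming rule 1, transferred against endogenous cells in IRF4 tumours gave medians of -0.86 (cytotoxic), -0.69 (inhibitory), 1.501 (stem) and -1.15 (proliferation), and lower counts of 18 (proliferation), and turned to medians of -0.18 (Myc). Class shares gave log2 ratios of 1.94 (CD8 T-like share) under naming rule 1, and turned to -0.032 (CD4 T-like share) under rule 2. Over cells with an Xist UMI, transferred cells gave medians of 0.12 (cytotoxic) and 0.61 (proliferation), and log2 ratios of 0.37 (Irf4). Over cells without an Xist UMI, transferred cells turned to medians of 0.0078 (inhibitory), and log2 ratios of -0.0088 (Irf4). Within cluster 4 alone, transferred cells gave higher counts of 5 (cytotoxic) and 2 (proliferation), and medians of 0.35 (cytotoxic), -0.29 (stem) and 0.26 (proliferation), and log2 ratios of 0.90 (Irf4), and turned to medians of 0.20 (inhibitory), 0.80 (cytokine) and -0.025 (respiratory chain), and log2 ratios of 0.80 (Ifng). Within cluster 7 alone, monocyte or macrophage-like cells gave medians of -0.97 (suppressive) and 0.39 (inflammatory), and turned to medians of 0.17 (MHC class II), 0.070 (proliferation), 0.049 (respiratory chain) and 0.080 (unfolded protein), and log2 ratios of 0.14 (Il7r) and 0.46 (Ifng). Within cluster 8 alone, monocyte or macrophage-like cells gave medians of -0.48 (MHC class II), -0.52 (suppressive) and 0.47 (inflammatory), and lower counts of 4 (suppressive), and turned to medians of 0.11 (proliferation), -0.028 (interferon-gamma), 0.049 (unfolded protein) and -0.17 (apoptosis), and log2 ratios of 0.23 (Lag3), 0.16 (Il7r), -0.80 (Gzmb) and 0.62 (Ifng). Within cluster 9 alone, monocyte or macrophage-like cells gave higher counts of 1 (MHC class II) and 5 (inflammatory), and medians of -1.17 (suppressive) and 0.59 (inflammatory), and turned to medians of 0.18 (MHC class II), 0.023 (proliferation), 0.53 (glycolysis), 0.15 (respiratory chain) and 0.073 (Myc), and log2 ratios of 0.53 (Cxcl3), 0.33 (Havcr2), 0.64 (Il7r) and -1.15 (Gzmb). Within cluster 14 alone, monocyte or macrophage-like cells gave medians of -0.42 (MHC class II), -0.027 (suppressive) and 0.33 (inflammatory), and lower counts of 1 (suppressive), and higher counts of 5 (inflammatory), and turned to medians of 0.048 (Myc), -0.16 (interferon-gamma), 0.061 (unfolded protein) and -0.035 (apoptosis), and log2 ratios of 0.26 (Mrc1), 0.79 (Spp1) and 0.065 (Ifng). Within clusters 1 and 11, endogenous CD8 cells gave lower counts of 7 (inhibitory) and 2 (stem), and higher counts of 2 (proliferation), and medians of 0.29 (proliferation), and turned to medians of 0.050 (stem), -0.047 (glycolysis) and -0.013 (unfolded protein), and log2 ratios of -0.053 (Gzmb). Without clusters 1, 11 and 12, mostly of endogenous cells, transferred cells gave higher counts of 1 (cytotoxic), and turned to medians of -0.068 (cytotoxic), 0.022 (inhibitory), -0.27 (residency), -0.12 (chemokine receptor) and 0.037 (Myc). Without cluster 0, transferred cells gave medians of -0.49 (stem). Without cluster 0, endogenous CD8 cells gave lower counts of 7 (inhibitory) and 2 (stem), and medians of -0.11 (stem) and 0.30 (proliferation), and higher counts of 1 (proliferation), and turned to medians of -0.013 (glycolysis), and log2 ratios of -0.053 (Gzmb). Without cluster 0, transferred against endogenous cells in control tumours gave medians of -1.74 (cytotoxic), -0.82 (inhibitory), 1.97 (stem) and -0.98 (proliferation), and turned to medians of -0.011 (respiratory chain). Without cluster 0, transferred against endogenous cells in IRF4 tumours gave medians of -1.14 (inhibitory), 1.42 (stem) and -0.61 (proliferation), and lower counts of 11 (proliferation). Without cluster 0, class shares gave log2 ratios of 2.197 (CD8 T-like share). With mixed cluster 5 added, transferred cells gave medians of -0.31 (stem). Without the highest doublet scores, transferred cells gave medians of 0.70 (proliferation), and endogenous CD8 cells -0.53 (stem). Without the highest doublet scores, monocyte or macrophage-like cells turned to log2 ratios of -0.66 (Pdcd1) and -0.82 (Gzmb). Without the cell richest in granzymes C to G, endogenous CD8 cells gave -0.40 (cytotoxic) and NK-like cells turned to log2 ratios of 1.13 (Havcr2).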

Other observations

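All tests of this part were chosen only after the results were seen. The immediate early genes Fos, Fosb and Dusp1, which respond within minutes to signals and to cell handling, were higher by at least 1.5 times in the IRF4 arm in all 6 endogenous classes examined, as was Egr1 in all but CD8 T-like cells (1.35), but these genes were picked from the rankings. Ratios of Fos were 2.01 in CD8 T-like, 2.05 in NK-like, 2.13 in CD4 T-like, 1.92 in B-like, 3.46 in monocyte or macrophage-like and 2.83 in cDC2-like cells. The early activation list of T cells, also run in each class, holds those genes, so its values are no check on them. Its medians were 0.20 in CD8 T-like, 0.52 in NK-like, 0.91 in CD4 T-like, 0.84 in B-like, 1.03 in monocyte or macrophage-like and 0.74 in cDC2-like cells. All lay at percentiles of 99.7 or more. The list had a lower member in CD8 T-like and cDC2-like cells (Nr4a3, 0.423 and 0.655) and in NK-like cells (Nr4a1, 0.562). Outside the picked genes, measured members had ratios of 0.423 to 1.40 in CD8 T-like and 0.562 to 1.73 in NK-like cells. In monocyte or macrophage-like cells these ratios ran from 1.01 to 2.58. The haemoglobin gene Hbb-bs, a transcript of red blood cells, stood at 11282 CPM in B-like cells and 5089 CPM in CD4 T-like cells of the control arm, with 0 UMIs in both classes of the IRF4 arm. In NK-like cells it was higher in the IRF4 arm, with a ratio of 1.96.

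Irf4 stood at nearly the same level in both transferred libraries (ratio 1.12, 0.994 to 1.27), although 1 of them is labelled as transduced with IRF4. Exchanged labels cannot be told apart from correct ones by this value, because 3' tags may miss the vector. The list of IRF4 partners and targets lay at percentile 99.7 of random lists in transferred cells and at 11.7 in endogenous cells. It lay above the middle 95% of random lists under 19 of 22 alternatives, but at 97.3 among cells without proliferation UMIs. It lay at 68.96 among Xist-positive cells and at 80.7 without clusters of mostly endogenous cells. The proliferation and glycolysis lists of transferred cells lay at 100, so this percentile cannot single out IRF4 targets. A missed vector transcript stays open. Little IRF4 RNA remaining in the sorted cells is also open and was not tested.

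The CD8 T-like share of endogenous cells was 3.09 (2.81 to 3.41) times as large in the IRF4 arm. More blood or lymphoid cells in the control library would not account for it alone, since the ratio was 2.65 (2.41 to 2.92) without B-like, pDC-like and neutrophil-like cells and cluster 13. Transferred cells sorted into the endogenous library would not either, since the ratio was 3.05 (2.77 to 3.36) without cells with a Trbv14 UMI. A lower yield of all other cells would move their shares alike, but with CD8 T-like cells left out (and CD4 T-like cells not used, after their value was seen) the ratio was 2.22 (2.01 to 2.46) for NK-like and 0.282 for B-like cells. A selective sort gate, and a greater entry or growth of endogenous CD8 T cells in the IRF4 arm as a biological hypothesis, stay open with 1 library per arm.

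In monocyte or macrophage-like cells the interferon lists were higher and the suppressive or repair list lower in the IRF4 arm. Without the highest doublet scores the 3 medians kept at least 101% (88.95 to 115) of their size. The doublet call did not work, so doublets stay open. Once control clusters were weighted to the mix of the IRF4 arm, 27.2% (23.8 to 32.8) of the interferon-gamma median, 45.4% (42.3 to 52.4) of the type I interferon median and 52.6% (47.2 to 54.1) of the suppressive median remained. Members of the interferon-gamma list lead cluster 8, so weighting takes away part of the list's difference. Its median was 0.73, -0.028, 0.51 and -0.16 in clusters 7, 8, 9 and 14, so mix and change within clusters cannot be told apart. The mix may be a response to interferon from T and NK cells, an untested hypothesis. Cell handling stays open because the early activation list was higher in these cells.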
